A study of Homo sapiens with 6 samples.

How the data were processed

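The study measured RNA by paired-end sequencing in NCI-H295R, an established human adrenocortical carcinoma cell line that makes adrenal steroids. Cells were transduced with lentivirus carrying a short hairpin RNA (shRNA) against TPD52 or a non-targeting shRNA, per the labels. There were 3 libraries in each group, here called shTPD52 and shCtrl, and group and replicate number were taken from the sample titles. Total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit, per the labels' protocols. The submitters' processing notes name HISAT2 2.2.1, featureCounts 2.0.3 and the GRCh38 (hg38) build, without saying which step each served. The annotation release, read filters and strand setting are not given in the sources used here. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

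The deposited table holds FPKM, that is reads scaled to gene length in kb and to library size, computed by the authors for 34869 genes in 6 columns, 1 per library. Reads per gene were worked back from the deposited FPKM, because each low value is a whole multiple of what 1 read is worth at that gene's length. The length was the union of the gene's exons in GENCODE release 29 where that gave whole reads in every library above 0. Otherwise a length that did so was searched for. The same lengths entered the correction for length described below. The library totals recovered this way ran from 29544341 to 38396624 reads. At least 99.99% of values above 0 came out whole within a tolerance of 0.02 reads. The choice of lengths brings this share about, so it does not check the recovery. The recovered reads summed to between 100.58% and 100.67% of those totals, and the cause of the excess was not tested. Odd numbers made up only 26.1% to 29.6% of the counts between 1 and 20, the pattern that counting each mate of a pair as a read would leave. That reading rests on the values, since no label states how pairs were counted. If it holds, the counts, depths and floor given here in reads stand for fewer independent fragments. A floor of 3 reads corresponds to between 0.039 and 0.051 FPKM for a gene of 2 kb, and it covers counting error only. Gene symbols were matched by identifier for 34803 genes (99.8%), and coordinates are those of GENCODE release 29 on GRCh38.

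Genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left 12782. The deposited FPKM were used without further scaling, and fold changes are differences of log2(FPKM + 0.5) between the group means, a scale that understates the change of genes with low values. The test was limma (version 3.58.1 in R 4.3.3), a linear model with a moderated, two-sided test and an intensity trend in the prior variance, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. TPD52 itself lies under the filter, so its value comes from a fit of the 12783 genes that result when it is added. CYP11B1 and HSD3B1 are under it too and were each added to a fit in the same way, a step chosen after the data were seen. Gene lists were tested with camera against all other genes, with a preset correlation of 0.01 between genes, for the 21 of 23 lists with at least 5 tested members, and adjusted over the lists. The same test with an estimated correlation and fry, which asks whether a list's genes move one way on balance, stand beside it. The comparison, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. That rule named TPD52, CAMKK2 and a set of steroidogenic genes, the 8 largest rises and the 8 largest falls among passing genes with non-overlapping groups and a higher group mean of at least 5 FPKM (leaving out names that are only a clone or locus identifier), and the 3 passing members of each list with the smallest p. Genes outside the rule are said to be so where they appear.

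Alternatives were pseudocounts of 0.1 and 1, no filter, a filter of 5 FPKM, median-ratio scaling, quantile normalization, limma without the variance trend or with a robust prior, the replicate number as a block, a minimum absolute log2 fold change of 1, and leaving out each library in turn. After the data were seen, 4 more were added for all results: removal of each library's trend on gene length and GC content (loess, span 0.3), limma-voom on the recovered reads, rescaling to reads outside mitochondrially encoded genes, and protein-coding genes only. The camera test was also repeated after the length and GC correction. Length and GC content were available for 12707 of the genes tested (99.4%). The scripts were tested on simulated data with known changes in 12786 genes drawn for the comparison of shTPD52 with shCtrl. They recovered 78.8% of changes of log2 0.5 and 97.9% of changes of log2 1, with 6% false calls, and the fitted change was 0.914 and 0.909 of the true one. Those reads were drawn independently for each gene, with the same dispersion for all genes and no trend on length or GC content. The rates therefore need not hold for the real libraries, which differ along length. A length trend planted in 1 simulated library gave a Spearman correlation of -0.818 with gene length before the correction and -0.007 after it. That trend was a straight line on log2 length, which such a correction removes by construction, and GC content was drawn at random. The outcome checks that the correction works as written, not how well it suits the real libraries.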

Results

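RNA from NCI-H295R adrenocortical carcinoma cells carrying an shRNA against TPD52 was compared with RNA from the same line carrying a non-targeting shRNA, with 3 libraries in each group. The depth recovered from the deposited FPKM was 34277939, 30582681 and 36885546 reads in shCtrl replicates 1, 2 and 3. In shTPD52 replicates 1, 2 and 3 it was 29544341, 36480354 and 38396624 reads. Reads of mitochondrially encoded genes made up 17.9% ± 0.53 (SD, n = 3) of the shCtrl libraries and 22.1% ± 2.37 (n = 3) of the shTPD52 libraries. The exact permutation p was 0.1, two-sided, the smallest that 3 against 3 libraries allow. The first principal component held 61% of the variance. On it shTPD52 replicate 2 lay at 0.29, apart from shTPD52 replicates 1 and 3 at 27.3 and 35.3 and from the shCtrl libraries between -24.1 and -16.4.

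The comparison asks how lowering TPD52, a gene the series title ties to aldosterone synthesis and CAMKK2 signaling, changes the transcriptome of these cells. TPD52 RNA was 1.30 ± 0.12 FPKM (SD, n = 3) in shCtrl and 0.640 ± 0.013 FPKM (n = 3) in shTPD52, 0.494 times the control level. With the knockdown, CYP11B2, which encodes aldosterone synthase, rose 2.64-fold in mean FPKM. HSD3B2, which encodes the adrenal 3-beta-hydroxysteroid dehydrogenase, rose 3.67-fold, and MC2R, the ACTH receptor, rose 3.54-fold. CACNA1H and CACNA1G, which encode T-type calcium channels, fell. By camera the lists of oxidative phosphorylation and cholesterol synthesis genes stood higher and that of Wnt targets lower, though 32 of 37, 19 of 24 and 9 of 17 members did not pass. None of these list calls held with camera at an estimated correlation (adjusted p = 0.727, 0.494 and 0.727). For the cholesterol list that correlation was -0.011, under the preset 0.01, so a higher correlation did not end its call. CAMKK2 RNA was 4.85 ± 0.34 FPKM in shCtrl and 4.64 ± 0.45 FPKM in shTPD52 (n = 3 each) and did not pass the test.

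TPD52 (ENSG00000076554, GRCh38 chromosome 8, 80034745 to 80231232, minus strand) stood at 1.42, 1.18 and 1.29 FPKM in shCtrl replicates 1, 2 and 3. In shTPD52 replicates 1, 2 and 3 it stood at 0.630, 0.635 and 0.655 FPKM, so every knockdown library was lower than every control library. The values rest on 292 to 396 recovered reads per shCtrl library and 151 to 204 per shTPD52 library. These stand for fewer fragments if each mate was counted as a read. TPD52 fell by 0.65 on the log2 scale (SE 0.14, limma with Benjamini-Hochberg adjustment, adjusted p = 0.0218). Its relatives did not pass, and the signs of both flip with median-ratio scaling. TPD52L1 had a log2 fold change of -0.10 (limma, adjusted p = 0.391) and TPD52L2, named after its values were seen, of -0.026 (limma, adjusted p = 0.819). The TPD52 call ended after the length and GC correction (log2 fold change -0.50, limma adjusted p = 0.0826), under a filter of 5 FPKM, without a filter, and without any 1 library other than shTPD52 replicate 2. Adjusted p over all 19 alternatives ran from 0.00437 to 0.0996.

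In all, limma with Benjamini-Hochberg adjustment called 2341 of 12782 genes, 720 higher and 1621 lower in shTPD52. Of these, 154 had an absolute log2 fold change of at least 1, 64 higher and 90 lower. The median log2 fold change of all tested genes was -0.11, and median-ratio scaling moved it to 0.00 and the split to 1083 higher and 1038 lower. Quantile normalization called 1152 genes higher of 2340, and the length and GC correction 1357 of 2699. The 3 libraries of shTPD52 did not overlap the 3 of shCtrl for 5372 genes (42%), where chance gives 10% on average. Genes of a library can shift together, so the excess does not measure effects gene by gene. The share was taken on unscaled values, and the median-ratio factors averaged 1.048 in shCtrl and 0.963 in shTPD52 (n = 3 each). The count of changed genes was 226, 450 and 87 without shCtrl replicates 1, 2 and 3. It was 159 and 897 without shTPD52 replicates 1 and 3, and 5825 without shTPD52 replicate 2.

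Among steroidogenic enzymes and cofactors, 5 of 15 tested genes rose, none fell and 10 did not pass. Adjusted over the list alone, 6 were higher and 2 lower. HSD3B2 (ENSG00000203859, GRCh38 chromosome 1, 119414931 to 119423035, plus strand) rose from 5.80 ± 0.77 to 21.3 ± 1.05 FPKM (SD, n = 3 each), a log2 fold change of 1.80 (SE 0.11, limma adjusted p = 0.00138). CYP11B2 (ENSG00000179142, GRCh38 chromosome 8, 142910559 to 142917843, minus strand) rose from 3.34 ± 0.37 to 8.80 ± 2.52 FPKM (n = 3 each), a log2 fold change of 1.24 (SE 0.19, limma adjusted p = 0.0115). These values rest on 317 to 338 recovered reads per shCtrl library and 549 to 1218 per shTPD52 library. SULT2A1, the DHEA sulfotransferase, rose by 0.46 and CYP21A2, the 21-hydroxylase, by 0.35 on the log2 scale. FDX1, the electron donor of the mitochondrial P450 enzymes and named after its values were seen, rose by 0.41. STAR, CYP11A1 and CYP17A1 did not pass. STAR, the cholesterol carrier of mitochondria, had a log2 fold change of -0.0094 (limma adjusted p = 0.955), its sign flipping with median-ratio scaling. CYP11A1 had 0.35 (limma adjusted p = 0.0532) and CYP17A1 -0.36 (limma adjusted p = 0.0565). CYP11A1 passed in 7 of 19 alternatives, among them the length and GC correction (0.44, limma adjusted p = 0.0133), and CYP17A1 in 5 of 19. CYP11B1, the cortisol-forming neighbour and near-identical copy of CYP11B2, was under the filter at 0.279 ± 0.142 FPKM in shCtrl and 0.985 ± 0.314 FPKM in shTPD52 (n = 3 each). Added to the fit it rose by 0.93 on the log2 scale (SE 0.22, limma adjusted p = 0.0296), a call held in 12 of 19 alternatives and in 1 of the 6 that leave out a library (adjusted p from 0.00969 to 0.11). HSD3B1, the copy of HSD3B2 and named after its values were seen, was listed at 0 in every shCtrl library and at 0.192 ± 0.113 FPKM in shTPD52 (n = 3 each). Reads can be exchanged within these pairs and between CYP21A2 and its pseudogene, so the level of each member is uncertain. As a list these genes stood higher than other genes (camera, adjusted p = 0.0281, and adjusted p = 0.494 with an estimated correlation). The estimated correlation was -0.038, under the preset 0.01, so the loss there did not come from a higher correlation. That call ended with quantile normalization and without shTPD52 replicate 3, with adjusted p from 0.00911 to 0.135 over 19 alternatives. Its risers numbered 1 without shCtrl replicate 1 or 3, 2 without shCtrl replicate 2 or shTPD52 replicate 1, and 7, beside 3 fallers, without shTPD52 replicate 2. CYP11B2 lost its call without shCtrl replicate 1 (log2 fold change 1.21, limma adjusted p = 0.0521) or shCtrl replicate 3 (1.20, adjusted p = 0.0667), with adjusted p from 0.00242 to 0.0667 over 19 alternatives.

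**Figure D1:**
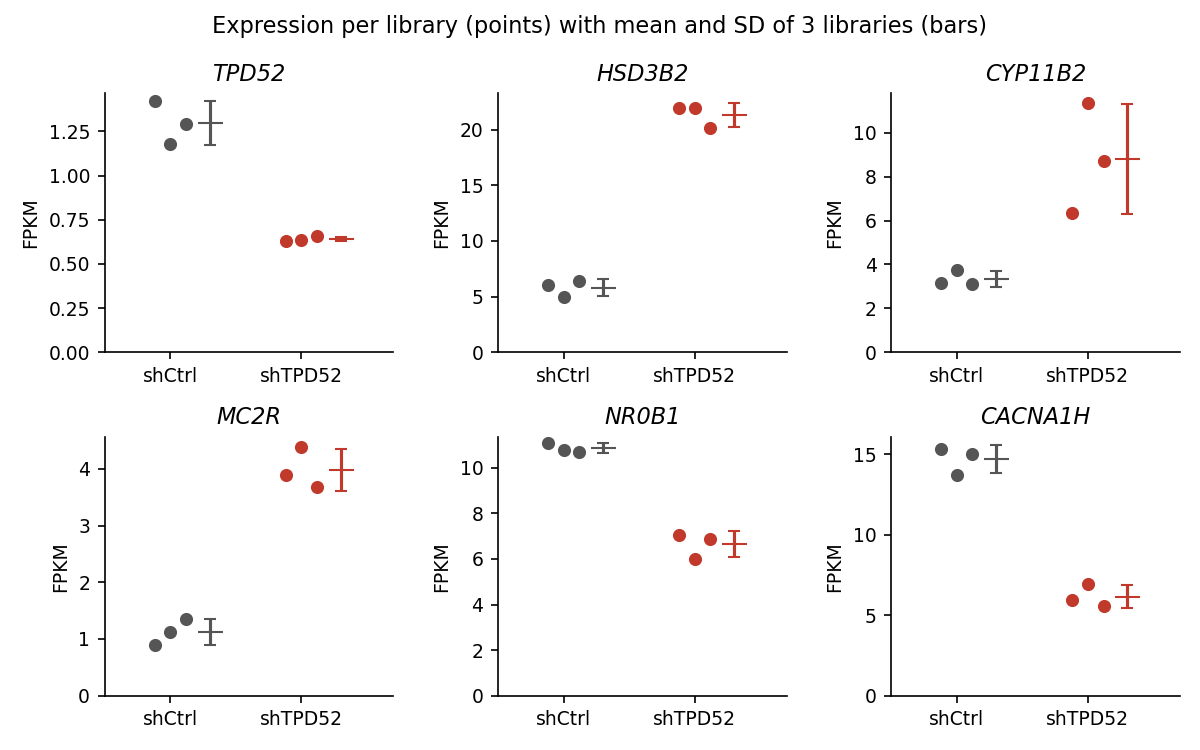
FPKM of 6 genes in each of the 3 shCtrl (grey) and 3 shTPD52 (red) libraries, with the mean and SD of each group beside the points. All 3 shTPD52 libraries lie below all 3 shCtrl libraries for TPD52, NR0B1 and CACNA1H and above them for HSD3B2, CYP11B2 and MC2R.

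Of the transcription factors of CYP11B2 and other steroidogenic genes, 2 of 16 fell, none rose and 14 did not pass, with the same 2 adjusted over the list alone. NR0B1 (DAX-1), a repressor of steroidogenic transcription, fell from 10.9 ± 0.21 to 6.65 ± 0.56 FPKM (n = 3 each), by 0.67 on the log2 scale (limma adjusted p = 0.00886). NR4A1, an orphan receptor that can drive HSD3B2 and CYP11B2, fell by 0.68 (limma adjusted p = 0.022). NR4A2 had a log2 fold change of -0.31 (limma adjusted p = 0.141), and NR5A1 (SF-1), named after its values were seen, of 0.034 (limma adjusted p = 0.76), a sign that flips with quantile normalization. The list did not pass (camera, adjusted p = 0.101; adjusted p = 0.727 with an estimated correlation). After the length and GC correction 1 member was higher and 4 lower. NR0B1 lost its call only without shCtrl replicate 3 (limma adjusted p = 0.0613). NR4A1 lost its call without a filter, without any 1 shCtrl replicate and without shTPD52 replicate 1 (adjusted p up to 0.0955), and its log2 fold change went to -0.41 after the length and GC correction.

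CAMKK2 (ENSG00000110931, GRCh38 chromosome 12, 121237691 to 121298308, minus strand) had a log2 fold change of -0.061 (SE 0.11, limma adjusted p = 0.698). Its sign flips with median-ratio scaling, with quantile normalization, after the length and GC correction, on rescaling to non-mitochondrial reads and without shTPD52 replicate 3, and adjusted p was between 0.145 and 0.984 over 19 alternatives. Of 13 calmodulin and calmodulin-dependent kinase genes, 3 fell, none rose and 10 did not pass, with the same number adjusted over the list alone. CAMK2G fell by 0.57, CAMKK1 by 0.52 and CAMKV by 0.43 on the log2 scale. The calls of CAMKK1 and CAMKV ended with median-ratio scaling. After the length and GC correction CAMK2G had a log2 fold change of -0.35 and kept its call, and CAMKK1 had -0.28 (limma adjusted p = 0.138), which left 1 gene lower on that list. Among AMPK subunits and upstream kinases, PRKAB2 fell by 0.76 and the other 6 of 7 tested genes did not pass, also adjusted over the list alone. Neither list passed (camera, adjusted p = 0.659 and 0.405; adjusted p = 0.727 for both with an estimated correlation).

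Among adrenal ion channels, pumps and receptors, 1 of 26 tested genes rose, 7 fell and 18 did not pass. Adjusted over the list alone, 1 was higher and 11 lower. After the length and GC correction 3 were higher and 7 lower, and the list's median log2 fold change went from -0.32 to -0.07. MC2R rose from 1.12 ± 0.23 to 3.98 ± 0.37 FPKM (n = 3 each), a log2 fold change of 1.47 (SE 0.14, limma adjusted p = 0.00378). CACNA1H and CACNA1G, which encode T-type calcium channels, fell by 1.20 and 0.87 on the log2 scale (limma adjusted p = 0.0037 and 0.0104). CACNA1G went to -0.56 after the length and GC correction and lost its call without shCtrl replicate 3 or shTPD52 replicate 1 (limma adjusted p up to 0.0667 over 18 alternatives). AGTR1, the angiotensin II receptor, named after its values were seen, had a log2 fold change of 0.13 (limma adjusted p = 0.536). The list did not pass (camera, adjusted p = 0.137; adjusted p = 0.727 with an estimated correlation). Of 14 tested zona glomerulosa markers, 3 rose, 4 fell and 7 did not pass (3 and 5 adjusted over the list alone). HSD3B2 and CYP11B2 were among the risers, while WNT4 fell by 1.01 and the neurofilament gene NEFM by 0.83 on the log2 scale. That list did not pass (camera, adjusted p = 0.696; adjusted p = 0.864 with an estimated correlation).

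Of 17 tested Wnt and beta-catenin targets, 8 fell, none rose and 9 did not pass; 10 were lower adjusted over the list alone. APCDD1 fell from 59.9 ± 2.63 to 31.6 ± 1.02 FPKM (n = 3 each), by 0.91 on the log2 scale (limma adjusted p = 0.00344). The ubiquitin ligase gene ZNRF3 fell by 0.77 and the transcription factor gene LEF1 by 0.45. The list stood lower than other genes (camera, adjusted p = 0.00219; adjusted p = 0.727 with an estimated correlation). That call ended under a filter of 5 FPKM, with adjusted p from 0.000144 to 0.0536 over 19 alternatives. Only 1 member was lower without a filter, without any 1 shCtrl replicate or without shTPD52 replicate 1, and 3 were without shTPD52 replicate 3. LEF1 went to -0.30 after the length and GC correction and kept its call. Of 24 cholesterol biosynthesis genes, 4 rose, 1 fell and 19 did not pass, the same numbers adjusted over the list alone. IDI1, isopentenyl diphosphate isomerase, and EBP, a sterol isomerase, each rose by 0.96 on the log2 scale (limma adjusted p = 0.00639 and 0.0236). LSS, lanosterol synthase, fell by 0.37, a call that ended with median-ratio scaling. This list stood higher (camera, adjusted p = 0.0442; adjusted p = 0.494 with an estimated correlation). That call ended under a filter of 5 FPKM or none and without shCtrl replicate 1, shCtrl replicate 2 or shTPD52 replicate 2, with adjusted p from 0.00751 to 0.228 over 19 alternatives. Only 1 member was higher and none lower without any 1 shCtrl replicate or shTPD52 replicate 1, 2 were higher without shTPD52 replicate 3, and 5 were higher and 5 lower without shTPD52 replicate 2. With quantile normalization 7 were higher and 1 lower, and after the length and GC correction 9 were higher and none lower. Of 20 genes of cholesterol uptake, storage and efflux, 3 fell, none rose and 17 did not pass, also adjusted over the list alone. The receptor gene LRP1 fell by 1.17, the lysosomal cholesterol transporter gene NPC1 by 0.64 and GRAMD1A by 0.32 on the log2 scale. The call of GRAMD1A held in 9 of 19 alternatives, ending with median-ratio scaling (-0.20) and after the length and GC correction (-0.092), where 2 members of the list were higher and 3 lower. NPC1 went to -0.39 after that correction and lost its call without a filter and without any 1 library other than shTPD52 replicate 2 (limma adjusted p up to 0.0926). Of 26 lipid droplet and fatty acid genes, 1 rose, 3 fell and 22 did not pass, also adjusted over the list alone. The desaturase gene FADS2 rose by 1.08, while ACLY fell by 0.53 and CPT1A by 0.49. After the length and GC correction 5 members were higher and 2 lower, the list's median turned from -0.079 to 0.081 and CPT1A lost its call (limma adjusted p = 0.0641), as it did with median-ratio scaling (limma adjusted p = 0.0517). Neither of these lists passed (camera, adjusted p = 0.247 and 0.851; adjusted p = 0.727 and 0.94 with an estimated correlation).

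Of 37 tested nuclear oxidative phosphorylation genes, 5 rose, none fell and 32 did not pass, the same numbers adjusted over the list alone. ATP5F1C, an ATP synthase subunit, rose from 101 ± 1.09 to 147 ± 14.2 FPKM (n = 3 each), a log2 fold change of 0.53 (limma adjusted p = 0.013). SDHD rose by 0.64 and UQCRB by 0.57. The list's median log2 fold change was 0.23 against -0.11 for all genes (camera, adjusted p = 1.1e-06; adjusted p = 0.727 with an estimated correlation). It passed camera in all 19 alternatives (adjusted p up to 0.00284), but its risers numbered 0 without shCtrl replicate 1 or 3 and 1 without a filter, shCtrl replicate 2 or shTPD52 replicate 1. Without shTPD52 replicate 2, 17 members were higher and 1 lower. Of the 13 mitochondrially encoded transcripts, 6 rose, none fell and 7 did not pass, and 7 were higher adjusted over the list alone. MT-ND3 rose by 1.32, MT-ND2 by 0.80 and MT-ND6, which lies on the opposite strand to the others, by 0.68 on the log2 scale. MT-CO1, named after its values were seen, had a log2 fold change of -0.11 (limma adjusted p = 0.496), its sign flipping with median-ratio scaling. Its log2 fold change ran from -0.61 to 0.015 over 19 alternatives, and it passed as lower only with quantile normalization (limma adjusted p = 0.01). This list stood higher (camera, adjusted p = 0.000241; adjusted p = 0.503 with an estimated correlation). That call ended after the length and GC correction (adjusted p = 0.0558) and with quantile normalization (adjusted p = 0.865), where 1 member rose and 3 fell. Its risers numbered 0 without a filter or shCtrl replicate 3, 1 without shCtrl replicate 1 or shTPD52 replicate 1, 2 without shCtrl replicate 2, 3 without shTPD52 replicate 3, and 9, beside 1 faller, without shTPD52 replicate 2.

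**Figure D2:**
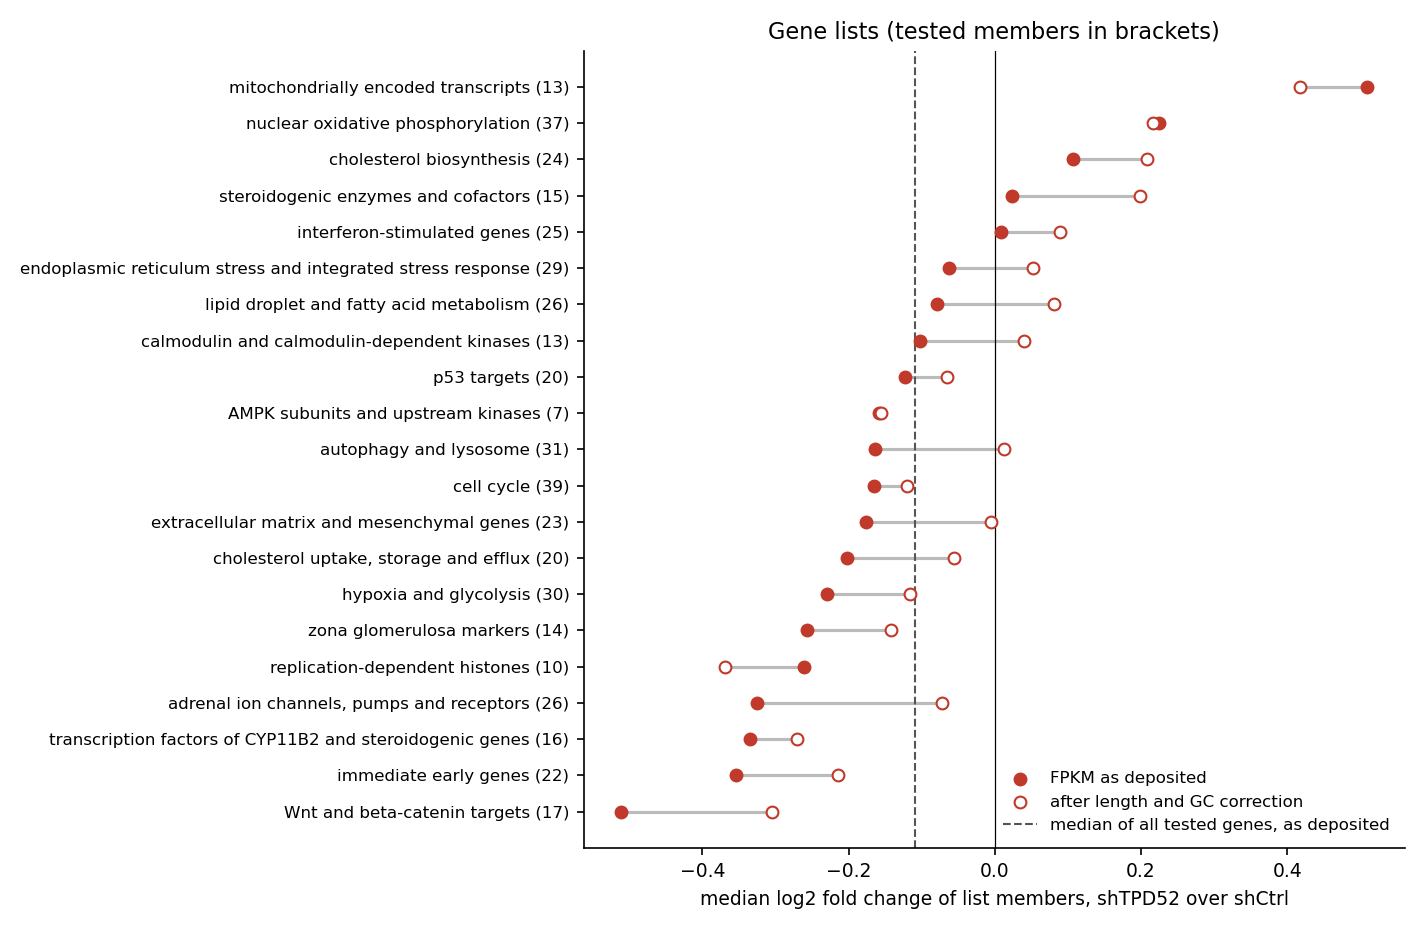
Median log2 fold change, shTPD52 over shCtrl, of the tested members of 21 gene lists, from the deposited FPKM (filled) and after the length and GC correction (open), with the median of all tested genes (-0.11) as a dashed line. The mitochondrially encoded transcripts lie highest at 0.51 and the Wnt and beta-catenin targets lowest at -0.51 in the deposited values.

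The remaining lists did not pass camera in the deposited values. Over all lists and alternatives, 185 of 437 counts of changed members moved by over 1.5 times. Of 39 cell cycle genes, 7 fell, none rose and 32 did not pass (8 lower adjusted over the list alone), with CCNB2 and FOXM1 each falling by 0.48 and KIF20A by 0.37. For that list camera gave an adjusted p of 0.0659 (adjusted p = 0.727 with an estimated correlation), and 0.00802 after the length and GC correction, within a range of 0.000144 to 0.213 over 19 alternatives. After that correction 1 member was higher and 10 lower, with median-ratio scaling 1 and 4. Of 30 hypoxia and glycolysis genes, 8 fell, none rose and 22 did not pass (1 higher and 12 lower adjusted over the list alone). ENO2 fell by 0.90, VEGFA by 0.64 and PFKL by 0.57 (list camera, adjusted p = 0.0856; adjusted p = 0.727 with an estimated correlation). After the length and GC correction 3 of these genes were higher and 3 lower, with median-ratio scaling 1 was higher and 4 lower, and PFKL lost its call after the correction (-0.27, limma adjusted p = 0.0531). VEGFA went to -0.32 there and kept its call. Of 22 immediate early genes, 4 fell, none rose and 18 did not pass (1 higher and 10 lower adjusted over the list alone). DUSP1 fell by 0.70 and JUN by 0.61 (list camera, adjusted p = 0.126; adjusted p = 0.727 with an estimated correlation). Of 23 extracellular matrix and mesenchymal genes, 2 rose, 6 fell and 15 did not pass (2 and 7 adjusted over the list alone). FN1 fell by 1.04, COL5A2 by 0.75 and ITGA5 by 0.68 (list camera, adjusted p = 0.488; adjusted p = 0.864 with an estimated correlation). After the correction 3 members of that list were higher and 4 lower, and ITGA5 went to -0.45. Of 31 autophagy and lysosome genes, 1 rose, 6 fell and 24 did not pass, also adjusted over the list alone. MITF fell by 0.74, FLCN by 0.60 and RRAGD by 0.43 (list camera, adjusted p = 0.336; adjusted p = 0.727 with an estimated correlation). After the correction 4 members were higher and 2 lower, camera's direction turned to up (adjusted p = 0.983) and FLCN lost its call (-0.32, limma adjusted p = 0.0927).

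Of 29 genes of endoplasmic reticulum stress and the integrated stress response, 5 rose, 2 fell and 22 did not pass (6 and 3 adjusted over the list alone). The chaperone gene HSP90B1 rose by 0.43, while ASNS fell by 0.87 and VLDLR by 0.55 (list camera, adjusted p = 0.459; adjusted p = 0.727 with an estimated correlation). VLDLR lost its call after the length and GC correction (-0.28, limma adjusted p = 0.0585). Its median log2 fold change was -0.06 while camera's direction was up. Of 25 interferon-stimulated genes, 3 rose, 1 fell and 21 did not pass (4 and 2 adjusted over the list alone). BST2 rose by 0.67 and IFITM1 by 0.60, while STAT2 fell by 0.69 (list camera, adjusted p = 0.242; adjusted p = 0.727 with an estimated correlation). After the length and GC correction 7 interferon-stimulated genes were higher and 1 lower. Of 20 p53 targets only CDKN1A passed, falling by 0.29, also adjusted over the list alone (list camera, adjusted p = 0.459; adjusted p = 0.727 with an estimated correlation). The call of CDKN1A ended with median-ratio scaling. Of 10 replication-dependent histone genes, 1 rose, 3 fell and 6 did not pass, also adjusted over the list alone. H2AC20 rose by 1.09, while H2BC11 fell by 0.77 and H3C10 by 0.58 (list camera, adjusted p = 0.78; adjusted p = 0.864 with an estimated correlation). After the length and GC correction 1 histone gene was higher and 5 lower of 9 with a corrected value. Of 18 markers of adrenal medulla, fibroblasts, endothelium and leukocytes in the table, 3 reached the filter and CHGB, a secretory granule gene, fell by 0.34 (limma adjusted p = 0.029), a call that ended with median-ratio scaling. Adjusted over the list alone, 2 were lower.

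Among the largest rises outside these lists was FATE1, a testis gene also expressed in adrenal cortex, from 4.44 ± 0.33 to 22.2 ± 2.85 FPKM (n = 3 each), 5.01-fold (limma adjusted p = 0.000884). SPRR1A, a cornified envelope gene, rose by 1.80, PAGE1 by 1.68, FAM166B by 1.57 and the cystatin gene CST1 by 1.55 on the log2 scale. Each of these 5 stayed past the threshold in every alternative it was tested in. MTATP8P1, a nuclear pseudogene copy of MT-ATP8, rose by 3.31 and the short noncoding RNA gene BCYRN1 by 1.54. Reads of both can come from near-identical copies, so these are uncertain. Among coding genes HSPG2 (perlecan) fell from 9.17 ± 0.46 to 3.08 ± 1.41 FPKM (n = 3 each), 0.336 times the control level (limma adjusted p = 0.0117). PLXNB3 and the insulin-like growth factor receptor gene IGF1R each fell by 1.29 on the log2 scale. The log2 fold changes of MIR4470, a Y RNA gene and the pseudogenes DNAJC19P5, TCAF1P1 and TUFMP1 were -1.88, -1.65, -1.72, -1.68 and -1.36. They are uncertain too, because reads can come from copies or, for MIR4470, because 1 to 16 reads per library were recovered.

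Fold changes followed gene length, here the length used to work back the reads, which need not be that of the expressed transcript. Among nuclear protein-coding genes, the median log2 fold change was 0.14 in the shortest eighth (1337 genes, up to 2394 bp) and -0.29 in the longest (1337 genes, from 10181 bp). In the former 199 genes were higher and 58 lower, in the latter 11 higher and 255 lower. The long genes HSPG2, LRP1, IGF1R and CACNA1H fell less after the length and GC correction, by 1.13, 0.79, 0.99 and 0.91, and kept their calls. Besides TPD52, 9 named genes lost theirs after it, all of them lower in shTPD52: CAMKK1, CAMKV, LSS, GRAMD1A, CPT1A, FLCN, VLDLR, PFKL and CHGB. With median-ratio scaling 9 named genes lost their calls, namely CAMKK1, CAMKV, LSS, GRAMD1A, CPT1A, KIF20A, CDKN1A, CHGB and MIR4470.

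**Figure D3:**
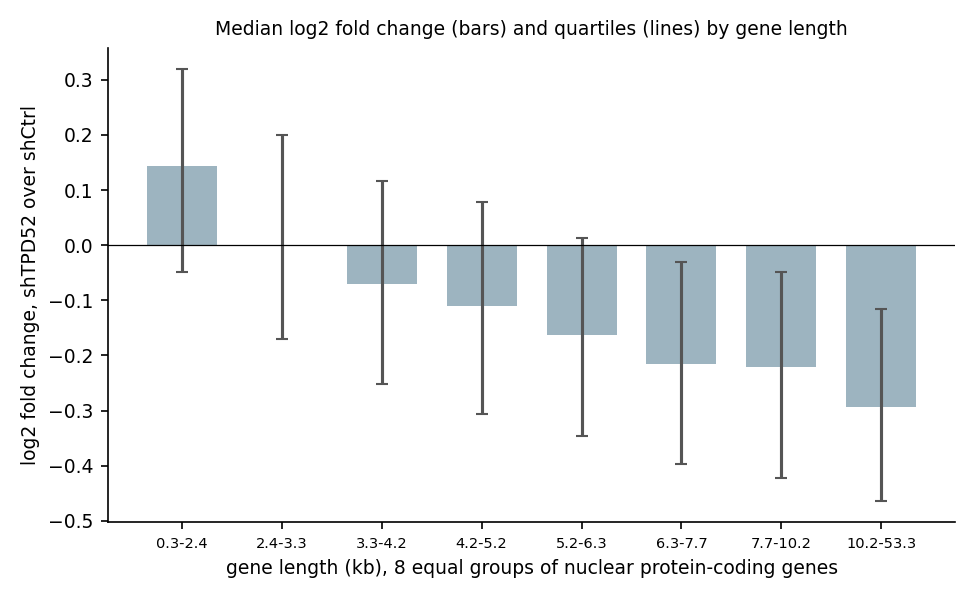
Log2 fold change, shTPD52 over shCtrl, in 8 equal groups of nuclear protein-coding genes ordered by gene length in kb; bars are medians and lines span the quartiles. The median goes from 0.14 in the shortest group to -0.29 in the longest.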

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

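The length and GC correction, limma-voom, non-mitochondrial rescaling and the protein-coding subset were chosen after the data were seen. Without a filter 531 genes passed (177 higher, 354 lower), and with an absolute log2 fold change of at least 1, 154 (64 and 90). Median-ratio scaling gave 1083 higher and 1038 lower, quantile normalization 1152 higher and the length and GC correction 1357 higher, the last of 2699, of which 1683 were shared with the 2341. Leaving out a library gave 87 (without shCtrl replicate 3) to 5825 genes (without shTPD52 replicate 2), 48 to 1616 of them higher and 39 to 4209 lower. Without 1 library a group is left with 2, and each gene's variance, pooled over both groups, then rests on fewer libraries. Fewer libraries alone cannot account for these counts, since the count rose to 5825 without shTPD52 replicate 2. TPD52 kept its direction in all 19 alternatives. It fell by 0.65 but missed the threshold without a filter and under a filter of 5 FPKM. In those fits the prior variance and the adjustment both rest on other genes. After the length and GC correction TPD52 fell by 0.50. With a library left out it ran from -0.70 to -0.60, and 5 of 6 fits missed the threshold. CYP11B2 stayed higher throughout, from 1.05 to 1.45 with a library left out. CAMKK2 reversed to 0.051 (median-ratio), 0.083 (quantile), 0.16 (length and GC) and 0.0088 (non-mitochondrial), and ran from -0.12 to 0.0038 with a library left out. STAR reversed to 0.11 (median-ratio), 0.11 (length and GC) and 0.067 (non-mitochondrial), with -0.10 to 0.047 on leaving out a library. TPD52L1 reversed to 0.023 (median-ratio) and 0.10 (length and GC), TPD52L2 to 0.093 (median-ratio), 0.079 (quantile), 0.11 (length and GC) and 0.048 (non-mitochondrial), NR5A1 to -0.054 (quantile; -0.010 to 0.077 with a library left out) and MT-CO1 to 0.015 (median-ratio). None of these reversals concerned a gene past the threshold in the deposited values. Counts of changed list members moved by over 1.5 times in 185 of 437 combinations of list and alternative. Of 21 lists, 5 passed camera; 12 passed without a filter, 3 under a filter of 5 FPKM, 0 with an estimated correlation, where limma called 4929 genes at an unadjusted p under 0.05, and 1 with fry, the steroidogenic list. Why results moved between the alternatives was not tested. Whether the replicate number pairs the samples is not settled. Deviations of same-numbered libraries correlated at 0.05, 0.25 and 0.02, and shCtrl replicate 1 correlated best with shTPD52 replicate 3 (0.28). The correlation of deviation with GC content, however, followed the number in both groups. It was 0.20, -0.40 and 0.28 in shCtrl replicates 1, 2 and 3, and 0.19, -0.42 and 0.39 in those of shTPD52. With the replicate block 3064 genes passed, 2202 of them shared with the 2341, and 5 lists. Depth limits low genes most: TPD52 rests on 151 to 396 reads per library.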

Other observations

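The gene families in this paragraph were chosen after the data were seen, and so were CYP19A1, PTGES and FBN2. The p-values of these families come from the same libraries, so they are descriptive and give no independent support. Cytosolic ribosomal protein genes stood higher with the knockdown: 36 of 80 rose and none fell, and 42 rose after the length and GC correction. Their median log2 fold change was 0.39 (camera, adjusted p = 3.33e-25; adjusted p = 0.26 with an estimated correlation). Of 75 mitochondrial ribosomal protein genes 18 rose and 1 fell (camera, adjusted p = 6.31e-14; adjusted p = 0.232 with an estimated correlation). Plexin and semaphorin genes, a family of guidance receptors and ligands, went the other way: 13 of 20 fell and none rose, and 9 fell after the correction. Their median was -0.48 before the correction (camera, adjusted p = 3.66e-06, and adjusted p = 0.263 with an estimated correlation) and -0.26 after it. Of 12 X-linked cancer-testis genes 5 rose, FATE1 and PAGE1 among them, and none fell (camera, adjusted p = 9.19e-06; adjusted p = 0.0711 with an estimated correlation). In the insulin-like growth factor axis 4 of 13 genes fell, IGF1R the most significant, and none rose; after the correction 2 fell and the median went from -0.38 to -0.17 (before it camera, adjusted p = 0.0677; adjusted p = 0.335 with an estimated correlation). Of 16 collagen genes 4 fell and none rose, but 3 rose and 2 fell after the correction (camera, adjusted p = 0.188 before it and 0.729 after it; adjusted p = 0.553 with an estimated correlation).

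CYP19A1, the aromatase gene, rose from 1.23 ± 0.21 to 3.59 ± 0.54 FPKM (n = 3 each), a log2 fold change of 1.24 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.00606). PTGES, a prostaglandin E synthase gene, rose from 1.64 ± 0.39 to 4.51 ± 0.48 FPKM (n = 3 each), also 1.24 on the log2 scale (limma adjusted p = 0.0075). FBN2, the fibrillin-2 gene, fell from 10.0 ± 1.01 to 4.10 ± 1.21 FPKM (n = 3 each), by 1.23 on the log2 scale (limma adjusted p = 0.0108), a call that ended without shCtrl replicate 3 or shTPD52 replicate 1 (adjusted p up to 0.0636 over 19 alternatives). CYP19A1 and PTGES passed in all 18 alternatives they were tested in. Of the genes named in the text, 91 were tested, 3 of them added to a fit from under the filter, and 80 passed. Of the 80, 14 lost their call only when a library was left out, 47 in another alternative, and 19 passed in every alternative, HSD3B2, MC2R, CACNA1H, WNT4, APCDD1, IDI1, FADS2, IGF1R and FATE1 among them.

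Tests written after their result was seen were those of the length pattern, the common mitochondrial change and the mitochondrial calls kept after the correction. The tests of the corrected fold changes, the paralog fold changes, the order of mitochondrial transcripts by length, and the splits were written before it.

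Long genes were lower and short genes higher with the knockdown. Libraries of the same group also differed along length, with correlations of deviation and length spread over 0.81 within shTPD52, from -0.39 in replicate 3 to 0.41 in replicate 2, and over 0.425 within shCtrl. A difference in RNA or library quality between single libraries may therefore account for much of the pattern, and an effect of TPD52 on long transcripts stays open and was not tested.

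HSD3B2, CYP11B2 and MC2R rose together. They kept 96.8%, 103% and 102% of their log2 fold change, and their calls, after the length and GC correction. Among nuclear protein-coding genes grouped by length, however, the median log2 fold change ran only from 0.14 to -0.29. Removing a smooth trend of that size could take little from these genes, whatever their cause. The kept shares show only that the average trend is too small to be the cause. They cannot decide whether an effect of length, GC content or RNA quality particular to these genes contributed, which stays open. Reads passed over from a near-identical copy were left undecided by the criterion set beforehand, which compared log2 fold changes: CYP11B1 had 0.93 (SE 0.22) where 2 SE above it had to lie under 0.62, and HSD3B1 0.46 (SE 0.23) where the bound was 0.90. With limma-voom CYP11B1 rose by 1.89 against 1.38 for CYP11B2, and HSD3B1 by 4.80 against 1.88 for HSD3B2. HSD3B1 was listed at 0 in every shCtrl library, so its fitted value depends on the prior count and decides nothing. In shTPD52 the recorded level of HSD3B1 was 1.24% of the FPKM gain of HSD3B2, and that of CYP11B1 18% of the gain of CYP11B2. How many of its reads a copy keeps is not known here, so reads of the copies stay open for HSD3B2 and CYP11B2. No copy was examined for MC2R. A biological effect of the knockdown also stays open. It is not separable here from an off-target effect, since the number of hairpins is not given in the sources used here.

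Mitochondrially encoded transcripts stood higher as a list. A common change in mitochondrial RNA content is argued against as the whole cause, since the 13 log2 fold changes ran from -0.26 to 1.32, a range of 11.1 times their median SE. Shorter transcripts had larger log2 fold changes (Spearman's rho across genes, which are not independent replicates, -0.516), past the bound of -0.5 set beforehand, though the permutation p was 0.0758, so the length-dependent difference between libraries may contribute. After the length and GC correction 6 of 6 called transcripts kept their call, and the list's median log2 fold change went from 0.51 to 0.42. The list's own camera call ended there (adjusted p = 0.0558). The correction, fitted over all tested genes, moved MT-ATP8, the shortest transcript, from 1.22 to 1.19 and MT-ND5, the longest, from -0.11 to -0.22. It did not narrow the gap between them, so the kept calls cannot decide whether the length-dependent difference is the whole cause. MT-ATP8 and its neighbour MT-ATP6 overlap, so their reads are not separable.

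The 2341 genes of the real grouping compare with 0 in each of the 9 other splits of the 6 libraries into 3 and 3, so 1 of 10 splits gave as many; 10 splits are too few for a share under 0.05.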
